A study of Mus musculus with 4 samples.

How the data were processed

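RNA of the mouse line Ba/F3 was measured on Affymetrix Gene 1.0 ST arrays after conversion to biotin-labelled sense-strand cDNA, per the labels' protocols. The 4 samples fall into 3 groups by their titles and descriptions: parental cells with IL-3 (n = 1), cells induced with doxycycline to express BCR-ABL without IL-3 (n = 2, A and B) and such cells with IL-3 (n = 1). All were grown to logarithmic phase, per the labels' protocols.

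The deposited values are log2 differences from the parental array, as read from the values themselves: the deposited parental column is 0 for all 28815 probe sets and the other columns have medians near 0. How the authors corrected background, normalized the arrays and summarised probes is not given in the sources used here, nor is the base of the logarithm. The base was read as 2 because 99.8% of the 86431 values other than 0 are whole multiples of 2 raised to minus 21, within the rounding of their printed digits or of single precision. That is the spacing of single-precision numbers between 4 and 8, the range of log2 array signals, so these values can be read as differences of 2 stored numbers between 4 and 16. The other 171 values are not such multiples. A probe set with a value that is an odd multiple of this step had a stored number below 8 on some array, which held for 11030 probe sets, called dim here. About 1576 dim probe sets are expected among the other 17785, where the parity hid them. Absolute levels, and signal over background, were not analysed here.

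Probe sets were named with the platform annotation: 21780 had 1 symbol, 1605 had several and 5430 were not listed. Of those with 1 symbol 21689 matched the RefSeq gene table (assembly GRCm38.p6) by gene identifier. Only probe sets with 1 symbol entered the comparisons, and the mean was taken for the 998 genes with several, which left 19935 genes.

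Lists, tests, thresholds, the naming rule and most alternatives were chosen before the data were examined, and assumed absolute levels. Because the values are differences, 3 settings were replaced: no filter on dim genes in place of a 30th-percentile filter, the mean of a gene's probe sets in place of the brightest, and no mean-variance trend. Random lists were matched on dim and other genes (2 classes) in place of mean expression.

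All 4 arrays were fitted in 1 limma model (version 3.58.1, R 4.3.3) with 3 group means. The only residual degree of freedom is the difference between A and B, and the lone arrays are assumed to vary like that pair. Empirical Bayes gave a prior of 16.38 degrees of freedom and a prior SD of 0.128. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. SE and intervals of 95% come from this fit. For the comparison of 1 array with 1 array the report gives values without p-values, and limma calls that borrow the spread of A and B are given among the alternatives. Size counts took genes for which every array of 1 group lay at least 2-fold from every array of the other. They are set beside the mean count over 100 simulations of pure noise. That noise was resampled from the differences between A and B, centred in dim and other genes apart, scaled to 1 array and given random signs. It therefore rests on this 1 pair of arrays.

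For each of 27 gene lists, the median of the members' log2 differences was computed. Limma's camera was run with a preset correlation of 0.01 and with an estimated one, adjusted over the lists within a comparison. The estimated one leaves 1 degree of freedom, and with it no list passed in either comparison. A list's failure under it therefore does not separate that list from the others. With the preset correlation the spread over genes, not that between arrays, sets the p-value. Where a list's genes vary together by more than 0.01, that p-value is too small. Estimated correlations were 0.18 for interferon-stimulated, 0.44 for mitosis and 0.58 for cholesterol synthesis genes. They were -0.037 for G1/S and -0.053 for ribosome biogenesis genes. With 1 degree of freedom, each reflects only how unevenly the members split into higher and lower on B than on A. A low value therefore does not show that a list's genes vary independently or that its preset p-value is sound. Calls of members are given over all genes and adjusted over the list alone. Some genes stand on several lists, such as Il2ra, Osm and Epor.

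The rule for named genes took in each comparison and direction the 8 genes with the widest gap among the called genes, filled from genes with a 2-fold gap where too few were called. It added up to 4 members of each list and 17 genes chosen by name, left out predicted genes, olfactory receptors and small RNAs, and kept them in all counts. List members that are named for not passing, or for passing over their list alone, lie partly outside this rule and were chosen after their values were seen.

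Alternatives were centring each array on its median, a threshold of 0.1, a fit of the 2 groups compared alone, a gap of 1.5-fold, leaving out A or B and, chosen after seeing the data, a robust prior, leaving out dim genes, and each probe set on its own. A gene was classed as dim where most of its probe sets were dim, so other genes can still hold a dim probe set. Leaving out dim genes is called without dim probe sets below. On 5 simulated data sets of 19935 genes with 200 changed genes, the fit called 99.8% of 2-fold changes and all 4-fold changes with IL-3 added, with 6.89% of calls false, and 99.6% of 2-fold changes with 5.03% of calls false against the parental array. Camera found a simulated shift of 0.3 in the G1/S list in 20 of 20 data sets, with a mean of 0.05 other lists called. These simulations draw genes independently, without the shared variation of real cultures. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.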

Results

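Ba/F3 is a mouse pro-B cell line that needs the growth factor interleukin-3 (IL-3) to survive and divide. BCR-ABL, the fusion tyrosine kinase of chronic myeloid leukaemia and the target of imatinib, can take over that role of IL-3. Transcript levels were measured on 4 Affymetrix Gene 1.0 ST arrays, which carry probe sets along whole transcripts. The parental line grown with IL-3 gave 1 array. A derived line, in which doxycycline at 500 ng/ml switches on BCR-ABL, gave 2 arrays without IL-3, called A and B, and 1 array with IL-3. The labels do not say whether A and B came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera p-values with the preset correlation compare a list's genes with all other genes, so genes and not arrays act as replicates. They do not show whether a list's shift would recur in other cultures. The submitters' aim was to find genes that BCR-ABL and the growth factor drive and that bear on imatinib resistance.

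The table holds 28815 probe sets, and the parental value is 0 in each of them. Every value is therefore a log difference from the parental array, read here as log2, and absolute levels were not analysed. The median difference was -0.0016 on array A, -0.064 on array B and 0.0029 on the BCR-ABL array with IL-3. After naming and averaging, 19935 genes were compared. The SD of the log2 differences over genes was 0.196 between A and B, 0.152 between A and the IL-3 array, and 0.222 between B and the IL-3 array. Against the parental array it was 0.323 for A, 0.361 for B and 0.316 for the IL-3 array. The number of arrays limits the precision of every value below.

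The first comparison set BCR-ABL cells without IL-3 (n = 2) against parental cells with IL-3 (n = 1), and asked how transcripts differ when the kinase replaces the growth factor. Leaving out predicted genes, olfactory receptors and small RNAs, the largest increase was in Il2ra, the alpha chain of the interleukin-2 receptor, which was 17.2-fold higher (log2 4.11, SE 0.15, adjusted p = 1.37e-11). BC023105, which the naming rule leaves out and which was chosen after its values were seen, was higher by 4.17 (log2). The interferon-induced protease Usp18 was 13.3-fold higher and the chemokine Ccl3 13.9-fold higher. Milr1, an inhibitory receptor of mast cells, rose 10.4-fold, the Schlafen gene Slfn2 10.2-fold, the antiviral genes Ifit1 and Ifit3 8.46-fold and 7.55-fold, and the survival kinase Pim2 7.88-fold. The largest decrease among all genes compared was in Far2, a fatty acyl-CoA reductase, which was 14.4-fold lower (log2 -3.84, SE 0.16, adjusted p = 5.42e-11). Rhag, a membrane protein of red cells, was 8.31-fold lower, the kallikrein Klk1b22 6.23-fold lower and the embryonic globin Hbb-y 5.87-fold lower. Rgs2, Gsta4, Tspan13 and Nme7 were 4.54-fold, 4.79-fold, 4.40-fold and 4.36-fold lower. The stored values of Milr1, Ifit3 and Hbb-y lay in the dim part of the scale on some array. In all, 1035 genes were called higher and 572 lower by limma at an adjusted p under 0.05. A and B lay on the same side of the parental array for all 1607. The test nearly ensures this, since its error is the A to B difference and the smallest called difference was 0.51 (log2). The gap to the parental array was at least 2-fold on both arrays for 180 higher and 81 lower genes, where simulated noise of the size of the A to B spread gave a mean of 3.59 in total. After each array was centred on its median the calls fell to 572 higher and 269 lower, and with B alone the 2-fold counts were 296 and 133. Of the genes of the naming rule given as called below, Epor, Sos1, Stat5b, Pik3cd, Rbl2, Txnip, Cdkn1b, Hsd17b7, Hdc, Cebpe, Gfi1b and Pecam1 lost their call under this centring. It also lowered the prior to 4.75 degrees of freedom, and the smallest adjusted p-values of single genes rose by many orders of magnitude. The very small limma p-values given for this comparison therefore hold only for the uncentred values. BCR-ABL, doxycycline, the derived line and the absence of IL-3 changed together in this comparison, and the spread of the lone parental array was taken to equal that of A and B.

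Interferon-stimulated genes had the highest median of the 27 lists in this comparison. Of 19 measured members 15 were called higher and 0 lower (16 and 0 adjusted over the list alone). The list's median was 1.56 (camera adjusted p = 3.31e-34, and adjusted p = 0.558 with an estimated correlation). Without dim probe sets it was 1.15, below that of cytokines and chemokines at 1.24. Oasl2 and Irf7, an antiviral oligoadenylate synthetase relative and the master transcription factor of the type I response, were at 2.27 and 2.11. Oas2, Rsad2 and Mx1 were at 1.84, 1.86 and 1.82. The members Irf1, Stat2 and Ifih1 did not pass, with values of 0.05, 0.07 and -0.16. On the BCR-ABL array with IL-3 the list's median against the parental array was 1.89.

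Of 15 STAT5 target genes 7 were called higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 3.75e-13, and adjusted p = 0.558 with an estimated correlation). Besides Il2ra and Pim2 these included the feedback inhibitors Cish (4.16-fold, adjusted p = 7.98e-08) and Socs1 (3.47-fold), the cytokine Osm (3.44-fold), the survival gene Bcl2l1 (log2 0.98) and the cyclin Ccnd2 (log2 0.71). Socs2 (0.16) and Pim1 (0.36) did not pass. Of 14 ERK feedback genes 7 were called higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 3.84e-09, and adjusted p = 0.558 with an estimated correlation). They included the phosphatases Dusp5 (4.73-fold) and Dusp6 (2.41-fold) and the transcription factor Etv5 (2.51-fold), while Dusp1 stood at -0.12 and did not pass. Of 23 immediate early genes 5 were called higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 6.61e-06, and adjusted p = 0.558 with an estimated correlation). Egr2 was 3.47-fold and Zfp36, which destabilises AU-rich messages, 2.22-fold higher, and Junb was at 0.71. Fos (0.03), Egr1 (-0.03) and Myc (0.18) did not pass. Of 14 NF-kB target genes 6 were called higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 6.61e-06, and adjusted p = 0.558 with an estimated correlation). Nfkbib, Nfkbie and Nfkbia, which encode inhibitors of NF-kB, were at 0.85, 0.76 and 0.76.

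Transcripts of secreted factors rose in part. Of 17 cytokines and chemokines 8 were called higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.40, or 1.24 without dim probe sets (camera adjusted p = 3.75e-13, and adjusted p = 0.558 with an estimated correlation). Il13 was 7.65-fold, Tnf 5.81-fold and Osm 3.44-fold higher, and Il4 and Lif were at 1.91 and 1.24. Il3 itself stood at -0.01 and Csf2 at -0.03, and neither passed. Of 16 cytokine receptors Il2ra, Il2rb (2.15-fold) and Il4ra (log2 0.78) were called higher and Epor, the erythropoietin receptor, lower (log2 -0.70), and the list as a whole was not called (median -0.07, mean 0.26, camera adjusted p = 0.376). The IL-3 receptor chains Il3ra (-0.51, adjusted p = 0.0539) and Csf2rb (-0.01) did not pass.

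The lists of ribosome biogenesis and G1/S genes were higher, and the list of FOXO targets and CDK inhibitors was lower. Of 19 ribosome biogenesis genes 14 were called higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 5.52e-20, and adjusted p = 0.558 with an estimated correlation). Rrp9 was 2.55-fold, the spermidine synthase Srm 2.44-fold and Bop1 2.22-fold higher. Of 27 genes of the G1/S transition and DNA replication 10 were called higher and 0 lower (15 and 0 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 1.88e-12, and adjusted p = 0.558 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was 2.74-fold and cyclin Ccne1 2.20-fold higher. The mitosis list was not called (median -0.05 over 19 genes, camera adjusted p = 0.376), and its 1 called member, Cenpf, was lower (log2 -0.71). Of 20 genes of the integrated stress response 13 were called higher and 0 lower (14 and 1 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 2.06e-14, and adjusted p = 0.558 with an estimated correlation). These included the serine and one-carbon enzymes Mthfd2 (log2 1.79), Psat1 (1.03) and Phgdh (1.02), asparagine synthetase Asns (1.41), and Nupr1 (1.77). Of 14 FOXO targets and CDK inhibitors 0 were called higher and 4 lower (0 and 7 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 6.67e-05, and adjusted p = 0.558 with an estimated correlation). The called members were Pik3ip1 (-0.81), the pocket protein Rbl2 (-0.68), the thioredoxin inhibitor Txnip (-0.88) and the CDK inhibitor Cdkn1b (-0.79).

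The BCL2 family went both ways and was not called as a list (median -0.12, camera adjusted p = 0.714). The anti-apoptotic genes Bcl2 (log2 0.99) and Bcl2l1 (0.98) were called higher, the pro-apoptotic Bcl2l11 was 2.70-fold lower (adjusted p = 1.02e-05), and Mcl1 (-0.22) did not pass. Of 4 drug transporters Abcb1b, a P-glycoprotein gene, was 3.61-fold higher (adjusted p = 3.24e-06), while Abcb1a, Abcg2 and Abcc1 did not pass at 0.18, 0.03 and 0.39. The list's median was 0.28, and 0.18 with B alone (camera adjusted p = 0.00655, and adjusted p = 0.558 with an estimated correlation). Of 12 adhesion and homing molecules the integrin Itga4 (3.80-fold) and the chemokine receptor Cxcr4 (2.18-fold) were called lower and 0 higher (3 lower adjusted over the list alone), with a median of -0.09, of -0.18 with B alone, -0.22 without dim probe sets and -0.05 after centring (camera adjusted p = 0.0139, and adjusted p = 0.558 with an estimated correlation). Of 21 components of BCR-ABL signalling, Sos1 (0.96) and Pik3cd (0.60) were called higher and Stat5b (-0.54) lower, and the list was not called (median -0.07). Of 18 genes of glycolysis and hypoxia Pdk1 was called lower (-0.93), and of 18 cholesterol synthesis genes Idi1 (0.58) and Hsd17b7 (0.59) higher, and neither list was called (medians -0.07 and 0.11). Of 14 p53 targets 3 were called higher and 2 lower, and the list was not called (median 0.04). Abl1 (-0.02) and Bcr (0.16), the partner genes of the fusion, did not pass. Where their probes lie relative to the transgene was not analysed here, so they do not test its expression.

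Markers of other blood and tissue cells mostly stayed near the parental level. Of 8 erythroid and megakaryocyte markers 0 were called higher and 3 lower (0 and 4 adjusted over the list alone), with a median of -0.26, or -0.44 without dim probe sets (camera adjusted p = 0.0108, and adjusted p = 0.558 with an estimated correlation). The called members were the erythroid transcription factors Klf1 (-0.92) and Gfi1b (-0.96), and Epor (-0.70). Of 16 mast cell and basophil markers Cpa3, a mast cell carboxypeptidase, was 8.21-fold higher, Hdc was at 0.74 and the chymase Cma1 was lower at -0.90, and the list was not called (median -0.14, mean 0.04). The lists of neutrophil and monocyte, B cell, T and NK cell and non-haematopoietic markers were not called, with medians of -0.02, -0.06, -0.12 and -0.04. The neutrophil median turned to 0.019 when each array was centred on its median. Called members were Cebpe, lower at -0.76, and Pecam1, higher at 0.59. Of 9 reference genes Gusb was called higher (0.58), and the list was not called (median 0.11, camera adjusted p = 0.0947). Centring each array on its median brought the reference and cholesterol lists past the threshold with the preset correlation, at 0.14 for each. With an estimated correlation neither list passed before centring. The cholesterol median was 0.02 with B alone and 0.20 with A alone.

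**Figure D1:**
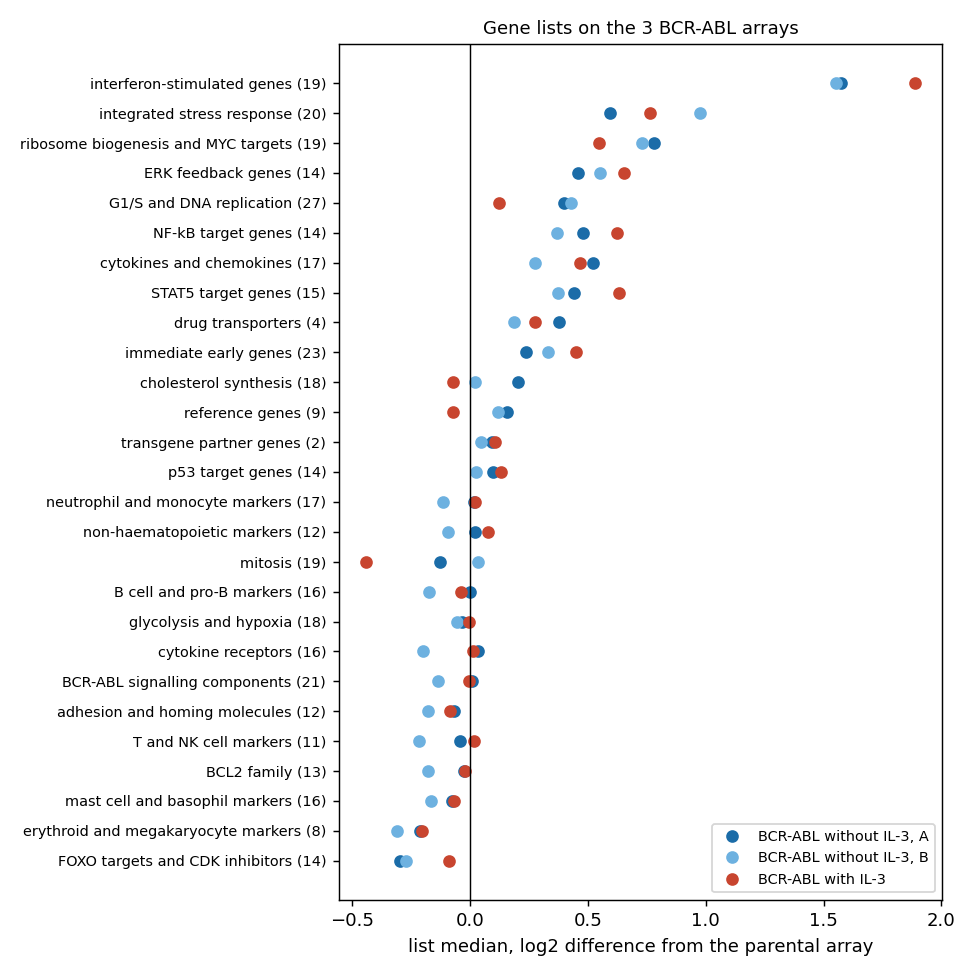
Median log2 difference from the parental array (horizontal axis) of each of 27 gene lists (vertical axis, number of measured genes in parentheses), with 1 point for each of the 3 BCR-ABL arrays. The interferon list lies farthest from 0, between 1.55 and 1.89, and the mitosis list falls to -0.44 on the array with IL-3.

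The second comparison set BCR-ABL cells with IL-3 (n = 1) against BCR-ABL cells without it (n = 2), and asked what the growth factor adds when the kinase is on. Taken gene by gene, limma called 1 of 19935 genes. That gene, the small nucleolar RNA Snord14e, was 2.40-fold higher (log2 1.26, SE 0.17, adjusted p = 0.0182). It falls outside the naming rule and was chosen after its values were seen, and it lost the call when each array was centred on its median. At an unadjusted p under 0.05 there were 901 genes, where 997 are expected by chance. At least 2-fold apart from both A and B were 1 higher and 0 lower gene, where simulated noise gave a mean of 3.22. Against B alone these counts were 10 and 28, and against A alone 7 and 4. On simulated data for this comparison with 200 changed genes 99.8% of 2-fold changes were called, with 6.89% of the calls false. With fewer changed genes the adjustment is stricter, so this share does not carry over to a comparison with 1 call. Far2, chosen after its values were seen, was 2.03-fold higher with IL-3 and was not called.

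Gene lists moved where single genes did not pass. Of 27 genes of the G1/S transition and DNA replication 26 were lower with IL-3, with a median of -0.36 (camera adjusted p = 6.25e-20, and adjusted p = 0.762 with an estimated correlation). Over all genes 0 members were called, and 13 were called lower when adjusted over the list alone, among them the helicase subunit Mcm7 (-0.57), the thymidylate synthase Tyms (-0.55), Gins1 (-0.60) and the thymidine kinase Tk1 (-0.52). All 19 mitosis genes were lower, with a median of -0.36 (camera adjusted p = 9.46e-19, and adjusted p = 0.762 with an estimated correlation). Of these 0 were called over all genes and 8 when adjusted over the list alone, among them the kinase Plk1 (-0.48), Cdc20 (-0.47) and Cenpe (-0.45). All 19 ribosome biogenesis genes were lower, with a median of -0.22 and 0 calls either way (camera adjusted p = 1.91e-10, and adjusted p = 0.762 with an estimated correlation). Of 18 cholesterol synthesis genes 16 were lower, with a median of -0.23 and 0 calls either way (camera adjusted p = 1.74e-08, and adjusted p = 0.762 with an estimated correlation). The 9 reference genes were lower too, with a median of -0.12 (camera adjusted p = 0.00362, and adjusted p = 0.762 with an estimated correlation). Between B and A the medians of the member differences were -0.0024 for G1/S, 0.14 for mitosis, -0.05 for ribosome biogenesis, -0.21 for cholesterol synthesis and 0.02 for the reference genes. Against A alone the medians were -0.24 for mitosis and -0.34 for cholesterol synthesis, and against B alone -0.45 and -0.14. Because A and B enter both comparisons, a list that was high in them by chance is pushed up in the first comparison and down in the second.

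Other lists were higher with IL-3. Over all genes the median difference of the IL-3 array was -0.0002 from A and 0.068 from B. Counts of higher members therefore include a small general lean to the higher side, and the share over all genes is not given here. Of 23 immediate early genes 20 were higher, with a median of 0.22 (camera adjusted p = 2.01e-06, and adjusted p = 0.762 with an estimated correlation). Over all genes 0 were called, and 5 when adjusted over the list alone, namely Zfp36 (0.65), Jun (0.54), Klf6 (0.50), Ier5 (0.49) and Fosl2 (0.47). Fos was 0.37 higher and did not pass. The ERK feedback list had a median of 0.10 (camera adjusted p = 0.0392, and adjusted p = 0.762 with an estimated correlation), and centring ended its call. Of its members Dusp1 (0.82) and Dusp10 (0.88), phosphatases that act on MAP kinases, passed when adjusted over the list alone (adjusted p = 0.000345 for both) and not over all genes (adjusted p = 0.175 for both). All 19 interferon-stimulated genes were higher, with a median of 0.15 (camera adjusted p = 1.53e-07, and adjusted p = 0.762 with an estimated correlation). Of these 0 were called over all genes and 4 over the list alone, Ifit3 (0.61), Mx2 (0.51), Irf7 (0.50) and Oasl2 (0.44). All 14 NF-kB targets were higher, with a median of 0.19 (camera adjusted p = 0.000279, and adjusted p = 0.762 with an estimated correlation), and Nfkbiz (0.57) and Nfkbia (0.50) passed over the list alone. The glycolysis and hypoxia list had a median of 0.10, or 0.05 after centring (camera adjusted p = 0.0149, and adjusted p = 0.762 with an estimated correlation) with 0 calls. The p53 list had a median of 0.13 (camera adjusted p = 0.0256, and adjusted p = 0.762 with an estimated correlation), and Gadd45a (0.73) passed over the list alone. Centring ended the call of the p53 list. T and NK cell markers were higher for all 11 genes, with a median of 0.13 (camera adjusted p = 0.0256, and adjusted p = 0.827 with an estimated correlation). Leaving out dim probe sets ended their call, at a median of 0.09. Between B and A the medians of the member differences were -0.15 for immediate early, -0.07 for ERK feedback, -0.11 for interferon, -0.12 for NF-kB, 0.08 for glycolysis, -0.07 for p53 and -0.20 for T and NK cell genes. The last of these was larger in size than the difference with IL-3. Against B alone the list medians were 0.24 for interferon, 0.17 for ERK feedback and 0.22 for T and NK cell genes, and against A alone they were 0.12 for NF-kB, 0.07 for p53 and 0.05 for T and NK cell genes.

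Among STAT5 targets 7 of 15 were called higher in BCR-ABL cells without IL-3 than in parental cells. With IL-3 added the list had a median of 0.05 and was not called (camera adjusted p = 0.608). Cish differed by 0.05 (95% interval -0.27 to 0.38), Pim2 by 0.15, Il2ra by -0.09 and Bcl2l1 by -0.07, and 1 member, Id1, was lower over the list alone (-0.64). Bcl2l11 differed by 0.26 and Mcl1 by 0.20, and the BCL2 family was not called (median 0.03). The integrated stress response was not called (median 0.05), and Ddit3 (0.94), Trib3 (0.71) and Cebpb (0.48) passed over the list alone. For Ddit3 the difference between A and B (1.14, B minus A) was larger than that with IL-3. Trib3 also differed between them, at 0.596 on A and 1.146 on B against the parental array. The passing of Ddit3 and Trib3 therefore does not separate an effect of IL-3 from the spread between A and B. For FOXO targets (median 0.14) Sesn1 was lower (-0.59) over the list alone, and for adhesion molecules (median 0.03) Cxcr4 (0.46) and Itga4 (0.47) were higher over the list alone, while neither list was called. Among neutrophil markers (median 0.06) Ngp was lower (-0.62) over the list alone. Cytokine receptors, cytokines, BCR-ABL signalling components, drug transporters, mast cell, B cell, erythroid, non-haematopoietic and fusion partner lists had medians between -0.06 and 0.07 and were not called. Under centring the medians of the B cell (-0.0084), fusion partner (-0.0082), adhesion (-0.011) and BCL2 family (-0.0093) lists changed sign. With 1 array on the IL-3 side, which was assumed to vary like A and B, these values carry no replicate check of their own.

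**Figure D2:**
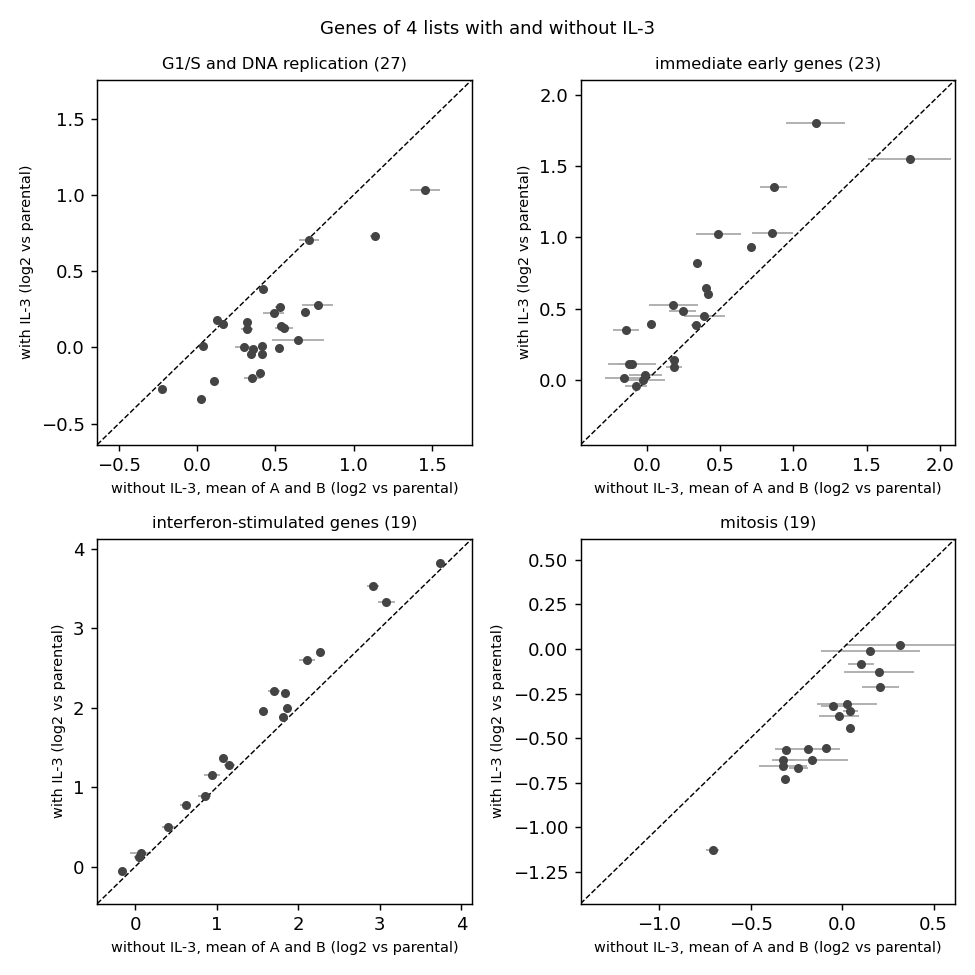
Log2 difference from the parental array with IL-3 (vertical axis, 1 array) against that without IL-3 (horizontal axis, mean of A and B with a bar from the lower to the higher value) for the genes of 4 lists. Points under the dashed line of equal values are lower with IL-3, as are 26 of 27 G1/S genes and all 19 mitosis genes, and points above it are higher, as are 20 of 23 immediate early genes and all 19 interferon-stimulated genes.

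The third comparison set BCR-ABL cells with IL-3 (n = 1) against parental cells with IL-3 (n = 1), so that IL-3 was present on both sides. It has no replicate of its own, and its values are given without p-values. Il2ra was 16.2-fold, Ccl3 15.6-fold, Usp18 14.2-fold, Ifit3 11.5-fold, Ifit1 10.1-fold, Slfn2 9.59-fold, Il13 9.27-fold and Pim2 8.75-fold higher. Rhag was 8.16-fold, Far2 7.09-fold, Klk1b22 5.68-fold and Hbb-y 5.25-fold lower, and the melanocortin receptor Mc5r, Nme7, the cytokine Il15 and the AMP deaminase Ampd3 stood at -2.17, -2.04, -2.03 and -1.85. At least 2-fold from the parental array were 219 higher and 103 lower genes, where simulated noise gave a mean of 12.95 in total and A differed from B by 2-fold in 25 genes. List medians were 1.89 for interferon-stimulated genes, 0.76 for the integrated stress response, 0.65 for ERK feedback, 0.63 for STAT5 targets, 0.62 for NF-kB targets, 0.55 for ribosome biogenesis, 0.12 for G1/S and -0.44 for mitosis.

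**Figure D3:**
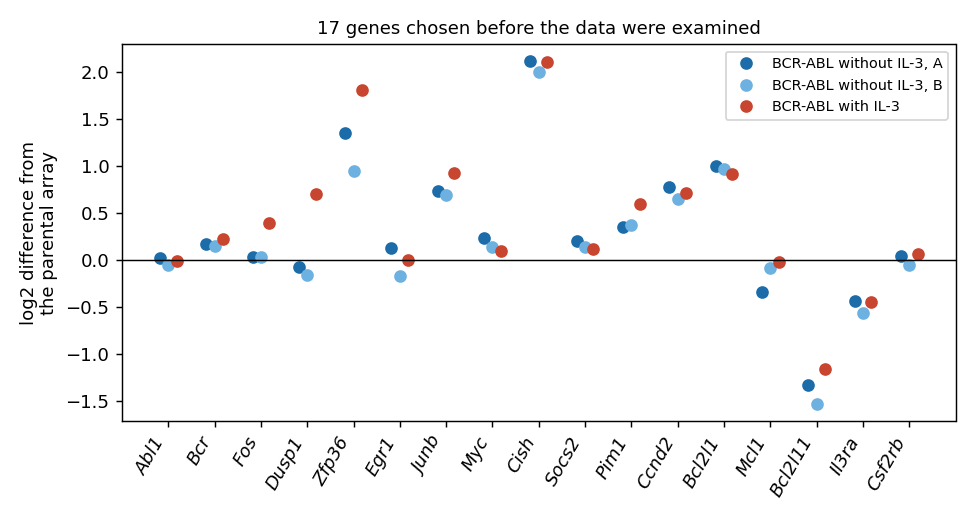
Log2 difference from the parental array (vertical axis) of 17 genes chosen by name (horizontal axis), with 1 point for each of the 3 BCR-ABL arrays. Cish lies near 2 and Bcl2l11 between -1.54 and -1.17 on all 3 arrays, while Dusp1 is at 0.70 on the array with IL-3 and at -0.08 and -0.17 without it.

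Finally, genes were counted for each of the 7 ways of parting the 4 arrays into 2 sets with a 2-fold gap between the sets. The 3 BCR-ABL arrays stood apart from the parental array for 144 genes that were higher in the BCR-ABL line and 63 that were lower, where simulated noise gave a mean of 2.82 in total. Among genes that the naming rule keeps, the higher ones with the widest gaps were Il2ra, Usp18, Ccl3, Slfn2, Milr1, Ifit1, Pim2 and Ifit3, and the lower ones Rhag, Far2, Klk1b22, Hbb-y, Nme7, Il15, Rgs2 and Gsta4. Arrays that shared IL-3 stood apart from those without it, whichever line they came from, for 0 genes, and without A for 5 higher and 17 lower genes. With a gap of 1.5-fold this way gave 7 genes (noise mean 0.35, at most 2). That was fewer than the other ways of setting 2 arrays against 2, which match no condition. They gave 9 (parental with A, noise mean 0.3, at most 2) and 14 (parental with B, noise mean 0.28, at most 3). At this gap A alone gave 9 genes against a noise mean of 40.38. The simulated noise therefore does not reproduce how these arrays vary, which limits every noise count given here. BCR-ABL and IL-3 together stood apart from all other arrays for 1 gene, Snord14e, where simulated noise gave a mean of 2.54 and at most 7. The ways that part A from B gave 3 genes for A alone (noise mean 2.76) and 11 for B alone (noise mean 3, at most 10). They gave 2 for the parental array with A (noise at most 0) and 0 for the parental array with B.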

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

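All tests in this part were chosen after seeing the data. Among 5430 probe sets that the platform annotation does not list, 28 (23 higher and 5 lower, 0.516%) lay at least 2-fold from the parental array on all 3 BCR-ABL arrays, a signal in data that the comparisons did not use. Among 1605 probe sets with several symbols 20 did so (16 higher and 4 lower, 1.25%), beside 150 higher and 66 lower of 21780 probe sets with 1 symbol (0.992%).

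As a list, interferon-stimulated genes had medians of 1.57, 1.55 and 1.89 on the 3 BCR-ABL arrays. With an estimated correlation the list was not called (camera adjusted p = 0.558), a setting whose 1 degree of freedom let no list pass. Members such as Irf1 (0.05), Stat2 (0.07) and Ifih1 (-0.16) did not pass. A shift of the whole scale is argued against, since the list exceeded the median of all genes by at least 1.57 on each array. A large share of neutrophils, monocytes or B, T, NK, erythroid or non-haematopoietic cells is argued against as well. Of 64 markers in 5 lists 0 were 2-fold higher on all 3 arrays, and the highest list median on any of them was 0.08. A small share of such cells stays open, because it need not raise a marker 2-fold. Among these markers, 9 of 17 for neutrophils and monocytes and 9 of 16 for B cells were dim. Mast cells or basophils in the cultures stay open, since 1 of their 16 markers, Cpa3, was 2-fold higher on all 3 arrays, and Hdc was called higher and Cma1 lower. Still open and untested are an odd parental array, a difference between array batches, and doxycycline or the making of the line, because BCR-ABL, itself an open explanation, changes together with all of them.

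The lists of G1/S, mitosis and ribosome biogenesis genes had lower medians when IL-3 was added. Over all genes limma called 0 of their members, and 901 of 19935 genes had an unadjusted p under 0.05. With an estimated correlation each list had a camera adjusted p of 0.762, where 1 degree of freedom let no list pass. A shift of the whole scale is argued against, since the weakest of the 3 list medians was -0.26 after each array was centred on its median. The 9 reference genes moved the same way under that centring (-0.16, camera adjusted p = 0.00123 with the preset correlation). With an estimated correlation their list did not pass before centring. A shift that depends on signal level therefore stays open, untested. Ordinary differences between cultures cannot be told apart from an effect of IL-3: A and B differed on these lists by at most 0.384 of the shift, and a lone pair does not show how far cultures grown on other days or to other densities vary. The single array with IL-3 also leaves a batch difference open, untested.

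Array B lay farther from A, with which it shares a condition, than the IL-3 array did, with SDs of 0.196 and 0.152. An offset of array B that depends on signal level stays open. After dimmer and brighter genes were centred apart the ratio of these SDs was 1.22 in brighter and 1.42 in dimmer genes, but the medians of dim and other probe sets on B, -0.077 and -0.0483, lie so close that this centring moved little, and trends within a class remain. A batch shared by A and the IL-3 array, a difference in handling and a difference between cultures stay open, untested. No biological explanation was tested.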

How the results depend on the processing

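The robust prior, the setting without dim probe sets and each probe set on its own were chosen after seeing the data. The other alternatives were not. A filter at the 50th percentile of expression, quantile normalization and a mean-variance trend were not run, because they need absolute levels. What signal over background limits was not analysed here.

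Of 54 list shifts 50 kept their side of the threshold when each array was centred on its median. ERK feedback (0.054) and p53 targets (0.0862) lost their call with IL-3 added, while cholesterol synthesis (0.1441) and reference genes (0.142) gained one against parental cells. Centring cut the calls against parental cells to 572 higher and 269 lower, all 841 of them among the 1607. The prior fell from 16.38 to 4.75 degrees of freedom and its SD from 0.128 to 0.103, and genes at an unadjusted p under 0.05 went from 3312 to 3319. Centring changes every A to B difference by the same constant, and these differences are the only measure of spread. The prior therefore moved because the offset between A and B (median -0.065, B minus A) was taken out. What caused that offset was not tested. Centring left 0 calls and 0 genes with a 2-fold gap for IL-3 added, 0 genes for BCR-ABL with IL-3 alone and 28 genes higher between A and B. Of 228 values of named genes 22 lost their call under centring, among them Snord14e, Ccne2, Trp53inp1, Mdm2, Gadd45a, Ddit3, Trib3, Dusp10 and the 12 genes named in the report, and 5 with the robust prior (Txnip, Cdkn1b, Gadd45a, Gfi1b and Ddit3), and at an adjusted p under 0.1 3 gained one.

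For IL-3 added the higher calls were 2 at an adjusted p under 0.1, 0 without dim probe sets and 3 with each probe set on its own, which gave 2 genes with a 2-fold gap. Without dim probe sets 52 of 54 list shifts kept their side, while T and NK cell markers (0.0944) lost their call with IL-3 and cytokines (0.1572) gained one. Medians against parental moved, among others, to 1.2382 for cytokines, 1.1545 for interferon, -0.4439 for erythroid and -0.2233 for adhesion genes. They also moved to 0.1632 for p53, -0.1433 for B cell and -0.106 for neutrophil genes. In this setting 9 genes were 2-fold higher between A and B. The causes were not tested. A fit of the 2 groups alone changed 0 calls. It could not change any, because the array left out is alone in its group and adds nothing to the estimate of spread.

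A gap of 1.5-fold is looser by construction. It gave 15 higher and 8 lower genes for IL-3 added, 634 and 344 for BCR-ABL without IL-3 against parental, 658 and 504 for BCR-ABL with IL-3 against parental, and 147 and 62 between A and B. For the parental array alone it gave 280 and 463, for BCR-ABL with IL-3 alone 11 and 2, and for the arrays with IL-3 against those without 3 and 4. Limma with the spread of A and B called 501 higher and 356 lower genes for BCR-ABL with IL-3 against parental.

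Leaving out A or B in turn, where fewer arrays must clear the gap, gave 7 to 10 higher and 4 to 28 lower genes for IL-3 added, and 220 to 296 higher and 112 to 133 lower against parental. It gave 4 to 5 and 1 to 2 for BCR-ABL with IL-3 alone, and 2 to 5 and 2 to 17 for the arrays with IL-3 against those without. List medians with IL-3 added ranged over 0.1651 to 0.2342 for immediate early, 0.1022 to 0.1726 for ERK feedback, -0.0373 to 0.0847 for STAT5, -0.2179 to -0.2084 for ribosome biogenesis, 0.0182 to 0.1133 for the BCL2 family, 0.1029 to 0.1384 for glycolysis, 0.1395 to 0.2372 for interferon, 0.0701 to 0.1512 for p53, 0.011 to 0.1132 for adhesion and -0.1661 to -0.1382 for reference genes. Other wide ranges were -0.4542 to -0.2377 for mitosis, -0.3446 to -0.1396 for cholesterol synthesis, 0.1248 to 0.2277 for NF-kB and 0.0547 to 0.2223 for T and NK cell genes. Signs changed, beside STAT5, for cytokine receptors (-0.0423 to 0.1584), cytokines (-0.0487 to 0.1925), B cell (-0.0196 to 0.1113), BCR-ABL signalling (-0.0437 to 0.0101), integrated stress response (-0.0239 to 0.0824), erythroid (-0.0037 to 0.1317), neutrophil (-0.0039 to 0.1371) and non-haematopoietic (-0.007 to 0.1026) genes, none of them called. Against parental cells they ranged over 0.2359 to 0.329 for immediate early, 0.3723 to 0.4386 for STAT5, -0.2974 to -0.2724 for FOXO, -0.0577 to -0.0359 for glycolysis, 0.026 to 0.0951 for p53, -0.1781 to -0.0668 for adhesion, -0.1647 to -0.0777 for mast cell, -0.1139 to 0.0158 for neutrophil and 0.1161 to 0.1553 for reference genes. They also ranged over 0.0217 to 0.2029 for cholesterol synthesis, -0.1796 to -0.0246 for the BCL2 family, -0.1732 to -0.0022 for B cell, -0.2153 to -0.0453 for T and NK cell genes, 0.2746 to 0.522 for cytokines, 0.1843 to 0.3769 for drug transporters and 0.595 to 0.9762 for the integrated stress response. Signs changed, beside neutrophil genes, for cytokine receptors (-0.2015 to 0.0318), mitosis (-0.1277 to 0.032), BCR-ABL signalling (-0.1386 to 0.0062) and non-haematopoietic genes (-0.0952 to 0.021), none of them called.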

Other observations

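All genes and the test in this part were chosen after seeing the data. Several genes with small p-values for IL-3 added did not pass the threshold over all genes. Far2, the fatty acyl-CoA reductase that fell most in BCR-ABL cells, was 2.03-fold higher with IL-3 than without (log2 1.02, SE 0.16, adjusted p = 0.0733) and stayed below the parental array at -2.83. Haem oxygenase Hmox1 (0.83), the placental growth factor Pgf (0.89) and the transcription factor Csrnp1 (0.71) were higher with IL-3, with adjusted p = 0.175, 0.266 and 0.296. Against parental cells these 3 genes were called higher without IL-3, at 0.75, 1.17 and 1.26.

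A and B, which share a condition, differed 2-fold in 25 genes. Simulated noise gave a mean of 13.54 and at most 29, but it was resampled from this same pair, so it is no independent reference. No test of single genes between A and B was made, because their difference is the only measure of spread. Higher on B were the olfactomedin Olfm3 (1.84), the collagenase Mmp8 (1.37), the Fc receptor subunit Ms4a2 (1.24) and the C-type lectin Clec4b2 (1.23), and lower were the arginine deiminase Padi2 (-1.54), the water channel Aqp8 (-1.22) and the gelatinase Mmp9 (-1.14). The stress gene Ddit3 stood at 0.49 on A and 1.63 on B against the parental array, and cyclin Ccng2 at -1.21 and -0.15. Ddit4, a brake on mTOR, stood at -1.03 and -0.19. Gains or losses of a whole chromosome in most cells of the line were tested as a candidate explanation for genes that differ from the parental array. Over 20 chromosomes with at least 305 genes each, no median over the brighter genes of a chromosome differed from the median over all brighter genes by more than 0.056 on any BCR-ABL array, which argues against it. Smaller segments and changes in a minority of cells were not tested.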
